A study of Mus musculus with 8 samples.

How the data were processed

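RNA sequencing was done on CD8+ T cells purified from spleens of naïve mice with a commercial mouse CD8+ T cell isolation kit, an enrichment on magnetic particles without a fluorescence sort. Per the labels, polyadenylated RNA was made into 8 libraries, 4 with the genotype label ATF4 Tg/Tg and the title ATF4 overexpression and 4 labelled WT. The sample titles of both groups call the cells naïve CD8 T cells. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 4 samples of a group came from separate mice, so p-values measure the spread between these samples, which may in part be technical. The design text names the mice differently from the sample labels, as ATF4Tg/Tg or E8IcreATF4Tg/Tg. These names read as transgenic without and with a Cre driver. The term WT is therefore used here only as the sample labels give it.

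The authors deposited 1 table of estimated counts per gene symbol, made with Salmon per the submitters' processing notes, on the mouse build GRCm38 p6. Salmon assigns each read pair to transcripts by probability, so reads shared between overlapping genes, paralogs or pseudogenes are divided by a model and can move from one to another. The annotation release, the strand setting and any trimming or filtering are not given in the sources used here. The table held 55291 genes, of which 30027 had no count in any library, and every column was mapped to 1 sample by its library name, with 0 columns unused. The estimated counts were rounded to whole numbers before testing. Symbols were matched to GENCODE M21 on GRCm38, where 53292 were found and 53186 named exactly 1 gene. Coordinates are given from that annotation, counted from 1.

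Total estimated counts per library ran from 93478668 to 125974114, which exceeds the number of clusters that the labels state as the target. This depth leaves sampling error small for most genes. Counts from amplified libraries without molecular identifiers are not independent molecules, so the intervals and floors given here cover counting error only. Where every library of a group had 0 counts, a fold was computed against a floor of 3 counts summed over that group. It is given as a lower bound, worded as at least that fold. This floor is a convention, and the lower end of a 95% exact binomial interval is smaller, for Aldh1l2 443-fold against 545-fold. Where a group had 1 to 3 counts in all, the ratio is given with its 95% exact binomial (Clopper-Pearson) interval.

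Groups were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term, TMM normalization, the filterByExpr filter and robust dispersion estimates. Of all genes, 16630 were tested, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM (counts divided by the TMM-scaled library size, times 1e6), computed from the deposited counts. Standard errors of log2 fold changes were derived from the F statistic. Fixed before the data were examined were the test, the alternatives except those named below as added, 31 gene lists and the rule for genes named in the text. That rule took Atf4, then, among called genes with a mean of at least 1 CPM in the higher group, no overlap between the groups and no provisional symbol, the 10 highest and 10 lowest log2 fold changes and the 5 smallest p-values in each direction. It also took up to 4 genes of each list with the smallest p-values, and, as checks, sex-linked genes and some T cell genes, among them Cd8a, Cd8b1, Cd4 and Cd44, which gave 141 genes. Genes outside the rule are said to be so.

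Gene lists with at least 4 tested members, 30 in all, were compared with all other tested genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. P-values were adjusted over the 30 lists. The list of sex-linked genes had only Xist tested and was not included. Of the 20 lists called, 9 were also called when the correlation was estimated per list. Lists overlap: 13 members of the ATF4 target list are also in another list. The test of the count table was tested on simulated data drawn from the real means and library sizes for this comparison, in which 15506 genes were tested. There 53.3% of 90 genes changed by 1 on the log2 scale and 72.3% of 94 genes changed by 2 were recovered, and 10 of 15322 unchanged genes were called. The shifted list was called and 0 of 30 random lists were. Each gene was simulated on its own, without library sets or correlation between genes. The random lists therefore do not test for false calls that arise from either.

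Replicates were compared before averaging. The chi-square per degree of freedom between libraries of the same group was at least 41.2, so no library was treated as a repeat of another. Libraries fell into 2 sets, replicates 1 and 2 against replicates 3 and 4 of each group, whose column names are also written differently. Within a group, libraries of the same set differed by a chi-square per degree of freedom of 41.2 to 71.3 and libraries of different sets by 146 to 250. The first principal component (44.8% of the variance) separated the groups and the second (19.6%) the sets. The deviations of same-numbered libraries from their group means correlated at 0.22, 0.20, 0.29 and 0.23 across genes, so the numbers were treated as pairing the samples. Libraries of the same set with different numbers correlated as well, at 0.16 to 0.25. The pairing therefore comes from the 2 sets rather than from single pairs. Libraries of different sets correlated at -0.27 to -0.16, but centring on group means forces negative values there once those within sets are positive. A fit with the replicate number as a block was planned as an alternative, and fits with the set as a block and within each set were added.

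In 4 libraries (WT replicates 1 and 4, ATF4 overexpression replicates 1 and 2) genes at 2 to 5 counts were few relative to genes at 10 to 13 counts, with ratios of 0.84 to 1.09 against 1.59 to 2.46 in the others. The cause of this gap was not tested, and a fit without these 4 libraries was added. It leaves 2 libraries per group that are not balanced over the sets. Further alternatives were RLE and upper-quartile factors, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, library sizes without mitochondrially encoded genes and Atf4, leaving out each library in turn, and for lists fry, camera with an estimated correlation and camera on voom values. Genes with a mean of at least 10 CPM were counted separately, as an addition. Ribosomal protein genes, globin genes, Klra genes and immunoglobulin genes have near-identical copies, and their single values are uncertain for that reason.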

Results

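The transcriptomes of splenic CD8+ T cells were compared between 4 libraries labelled ATF4 overexpression and 4 libraries labelled WT. ATF4 is the transcription factor through which the integrated stress response raises amino acid uptake and synthesis, and the series concerns its persistence in CD8+ T cells of tumors. The cells measured here came from naïve mice without a tumor, so the comparison asks what forced ATF4 expression does to CD8+ T cells at rest. WT libraries held 93478668, 108297485, 122033354 and 125974114 estimated counts, and ATF4 overexpression libraries held 119995444, 103741822, 114724777 and 113372470 (replicates 1 to 4). Between 17446 and 20338 genes had at least 1 count. Mitochondrially encoded genes took 2.57% to 3.72% of the counts. Xist was present in every library, at 935 ± 345 CPM in WT and 970 ± 161 CPM in ATF4 overexpression (SD, n = 4), and did not pass the test (adjusted p = 0.93).

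Atf4 itself (chromosome 15, 80255184 to 80257541, plus strand, GRCm38) was at 231 ± 76.4 CPM in WT and 328 ± 125 CPM in ATF4 overexpression (SD, n = 4). Its log2 fold change of 0.51 ± 0.31 (SE) did not pass the test (adjusted p = 0.37), and an exact two-sided permutation test over 70 assignments gave p = 0.23. The spread was mainly between the 2 library sets. In set 1, WT libraries were at 285 and 308 CPM and ATF4 overexpression libraries at 445 and 427 CPM. In set 2, WT libraries were both at 165 CPM and ATF4 overexpression libraries at 228 and 212 CPM. With the replicate number as a block the log2 fold change was 0.48 (adjusted p = 2.2e-04), and within the sets it was 0.59 (adjusted p = 0.0038) and 0.41 (adjusted p = 0.0046). Permuting within the sets gave p = 0.056, the smallest that an exact test of 36 such assignments can give. Without the 4 libraries that lack low counts Atf4 was at -0.11 (adjusted p = 0.86), where 1 WT library of set 1 and no ATF4 overexpression library of set 1 remain. The table gives 1 value per gene, so reads of a transgene and of the endogenous gene are not separated.

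The groups differed widely. In ATF4 overexpression 1524 genes were higher and 813 were lower (edgeR, adjusted p below 0.05), of 16630 tested. Of these, 1169 rose and 87 fell by at least 2-fold. Genes with a mean of at least 10 CPM gave 501 higher and 698 lower, so most of the genes that rose were of low abundance. Groups did not overlap in 22.0% of the tested genes, where chance gives 2.86%. With the replicate block 2279 genes were higher and 2237 lower, which moved the share of higher calls from 65.2% to 50.5%. Within set 1 the counts were 1161 and 528, within set 2 they were 2434 and 1365, and without the 4 libraries that lack low counts they were 1250 and 333.

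**Figure D1:**
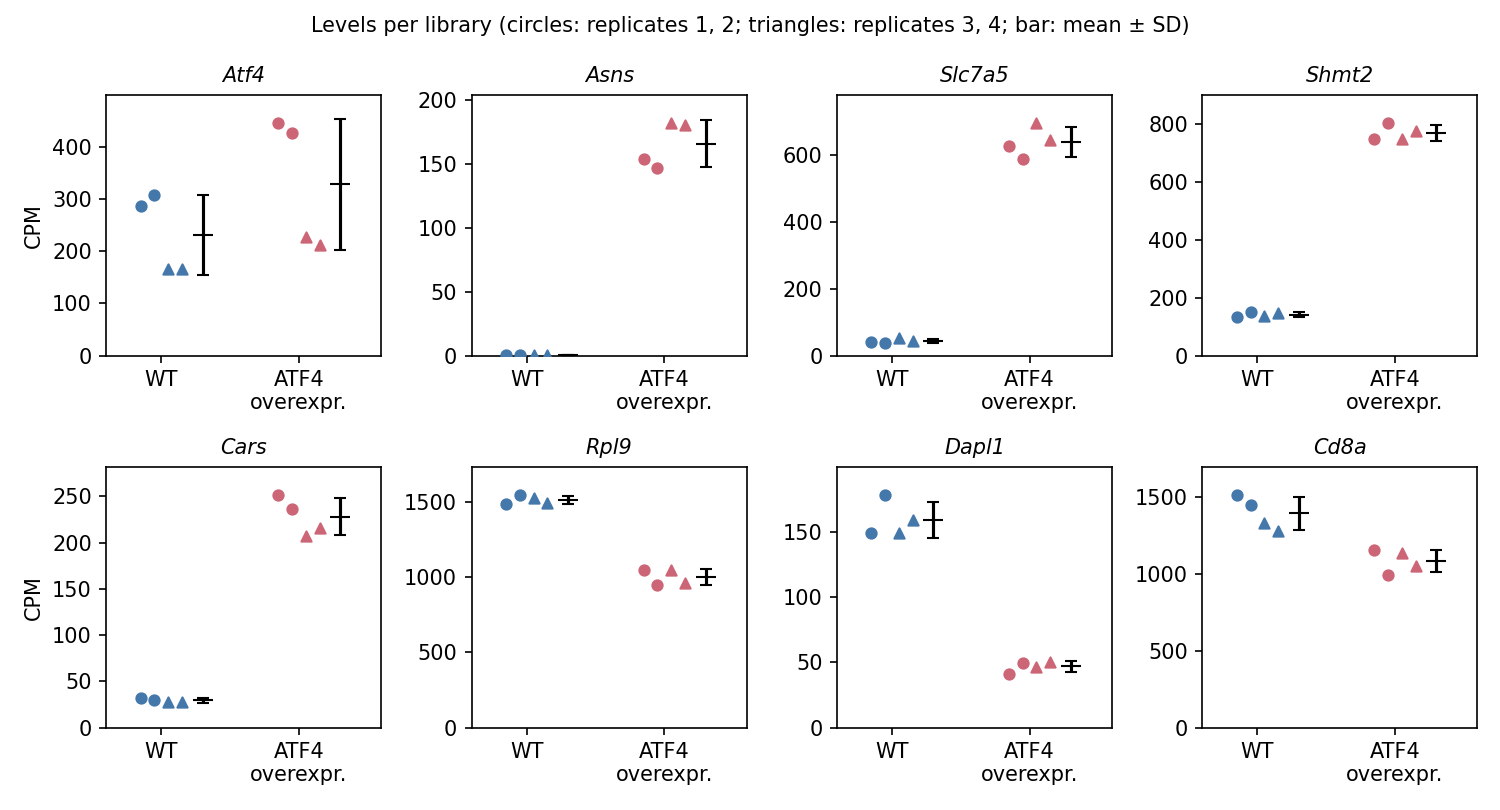
Level in CPM (linear axes from 0) of 8 genes in each of the 4 WT libraries (blue) and 4 ATF4 overexpression libraries (red), with circles for replicates 1 and 2, triangles for replicates 3 and 4, and a bar for the mean ± SD of each group. Atf4 differs more between the library sets than between groups, while Asns, Slc7a5, Shmt2 and Cars are higher and Rpl9, Dapl1 and Cd8a lower in all 4 ATF4 overexpression libraries.

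Known ATF4 targets rose together. Of 26 tested members of the list of ATF4 and integrated stress response targets, 23 rose and 0 fell (24 rose when adjusted over the list alone). The list median was 3.38 on the log2 scale, also with genes at 0 set to their bound (camera, adjusted p = 2.1e-30; adjusted p = 0.0015 with an estimated correlation). Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254), went from 0.307 ± 0.104 to 166 ± 18.2 CPM (log2 fold change 9.10 ± 0.21, adjusted p = 1.1e-08). Trib3, a pseudokinase induced by ATF4, rose by 5.84 ± 0.18 on the log2 scale to 71.7 ± 9.87 CPM. Eif4ebp1, an inhibitor of cap-dependent translation, rose by 3.36 ± 0.11 on the log2 scale from 4.36 to 44.9 CPM. Sesn2, which restrains mTORC1 when amino acids are short, rose by 3.38 ± 0.16. Chac1, a glutathione-degrading enzyme, had 3 counts over the 4 WT libraries and 13830 over the 4 ATF4 overexpression libraries, a ratio of 4199 (95% interval 1437 to 20366). The 3 members that did not pass, named here after their values were seen, were Atf3 (log2 fold change 3.58, adjusted p = 0.060), Ddit4 (0.86, adjusted p = 0.44) and Ppp1r15a (-0.05, adjusted p = 0.98).

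Genes of serine, one-carbon and amino acid synthesis were higher in 16 of 21 tested members and lower in 1. Adjusted over the list alone the counts were also 16 and 1. The list median was 1.83 (camera, adjusted p = 3.2e-16; adjusted p = 0.029 with an estimated correlation). Shmt2, the mitochondrial serine hydroxymethyltransferase, rose from 141 ± 8.02 to 769 ± 26.4 CPM (log2 fold change 2.44 ± 0.07, adjusted p = 5.7e-08). Aldh18a1, which starts proline synthesis from glutamate, rose by 1.83 ± 0.08, and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, by 3.39 ± 0.16. Aldh1l2, a mitochondrial folate enzyme, had 0 counts in all WT libraries and 3.79 ± 0.63 CPM in ATF4 overexpression, at least 545-fold higher. Cth, cystathionine gamma-lyase, likewise went from 0 counts to 2.56 ± 0.37 CPM, at least 370-fold higher.

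Amino acid transporters were higher in 11 of 15 members and lower in 0 (12 higher over the list alone), with a median of 1.61 (camera, adjusted p = 2.7e-10; adjusted p = 0.0085 with an estimated correlation). Both chains of the large neutral amino acid transporter rose: Slc7a5 from 42.7 ± 6.03 to 637 ± 44.9 CPM (log2 fold change 3.90 ± 0.11, adjusted p = 5.7e-08) and Slc3a2 from 109 ± 6.31 to 397 ± 18.5 CPM. Slc1a4, a transporter of alanine and serine, rose from 0.758 to 73.4 CPM, and Slc6a9, the glycine transporter, from 0.186 to 54.9 CPM. Cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA, were higher in 13 of 20 members and lower in 0, with a median of 1.10. Over the list alone 13 were higher and 1 was lower. The camera test of this list gave an adjusted p of 2.3e-11, and its call was lost with an estimated correlation (adjusted p = 0.075). Cars had the smallest p of the list, with a rise of 2.96 ± 0.09 (adjusted p = 5.9e-08), and Yars, Mars1 and Nars rose by 2.01, 1.88 and 1.56. The mean log2 CPM difference was 3.86 in both library sets for the target list, and 2.45 in set 1 and 2.69 in set 2 for the transporters.

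Transcripts of cytosolic ribosomal proteins fell together. Of 81 tested, 76 were lower and 0 higher (77 lower over the list alone), with a median of -0.58 (camera, adjusted p = 6.3e-38; adjusted p = 0.029 with an estimated correlation). Rps15a fell from 1566 ± 64.2 to 909 ± 80.0 CPM, Rpl35a from 912 ± 43.2 to 580 ± 7.40 CPM and Rpl9 from 1514 ± 27.5 to 1001 ± 52.8 CPM. The 5 members that did not pass, named after their values were seen, were the copies Rpl32l, Rpl39l, Rpl6l, Rps27l and Rps4l. Mitochondrially encoded genes had a median of -0.28 with 1 of 13 members lower (0 over the list alone), mt-Co1, whose call held only without WT replicate 3 or ATF4 overexpression replicate 2 among the 8 fits without 1 library (adjusted p between 0.023 and 0.13). Their camera call (adjusted p = 0.018) was lost with an estimated correlation (adjusted p = 0.34), with fry (adjusted p = 0.077), within set 2 (adjusted p = 0.11) and without the 4 libraries that lack low counts (adjusted p = 0.090). The replicate block called 4 members lower, mt-Nd1 (-0.29, adjusted p = 0.0019) and mt-Nd2 (-0.50, adjusted p = 5.8e-04) among them. With the library set as the block neither mt-Nd1 (adjusted p = 0.35) nor mt-Nd2 (adjusted p = 0.17) was called. The call of mt-Co1 was also lost with RLE factors (adjusted p = 0.068), upper-quartile factors (adjusted p = 0.093) and the stricter filter (adjusted p = 0.065), within set 1 (adjusted p = 0.085) and set 2 (adjusted p = 0.078) and without the 4 libraries that lack low counts (adjusted p = 0.19).

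**Figure D2:**
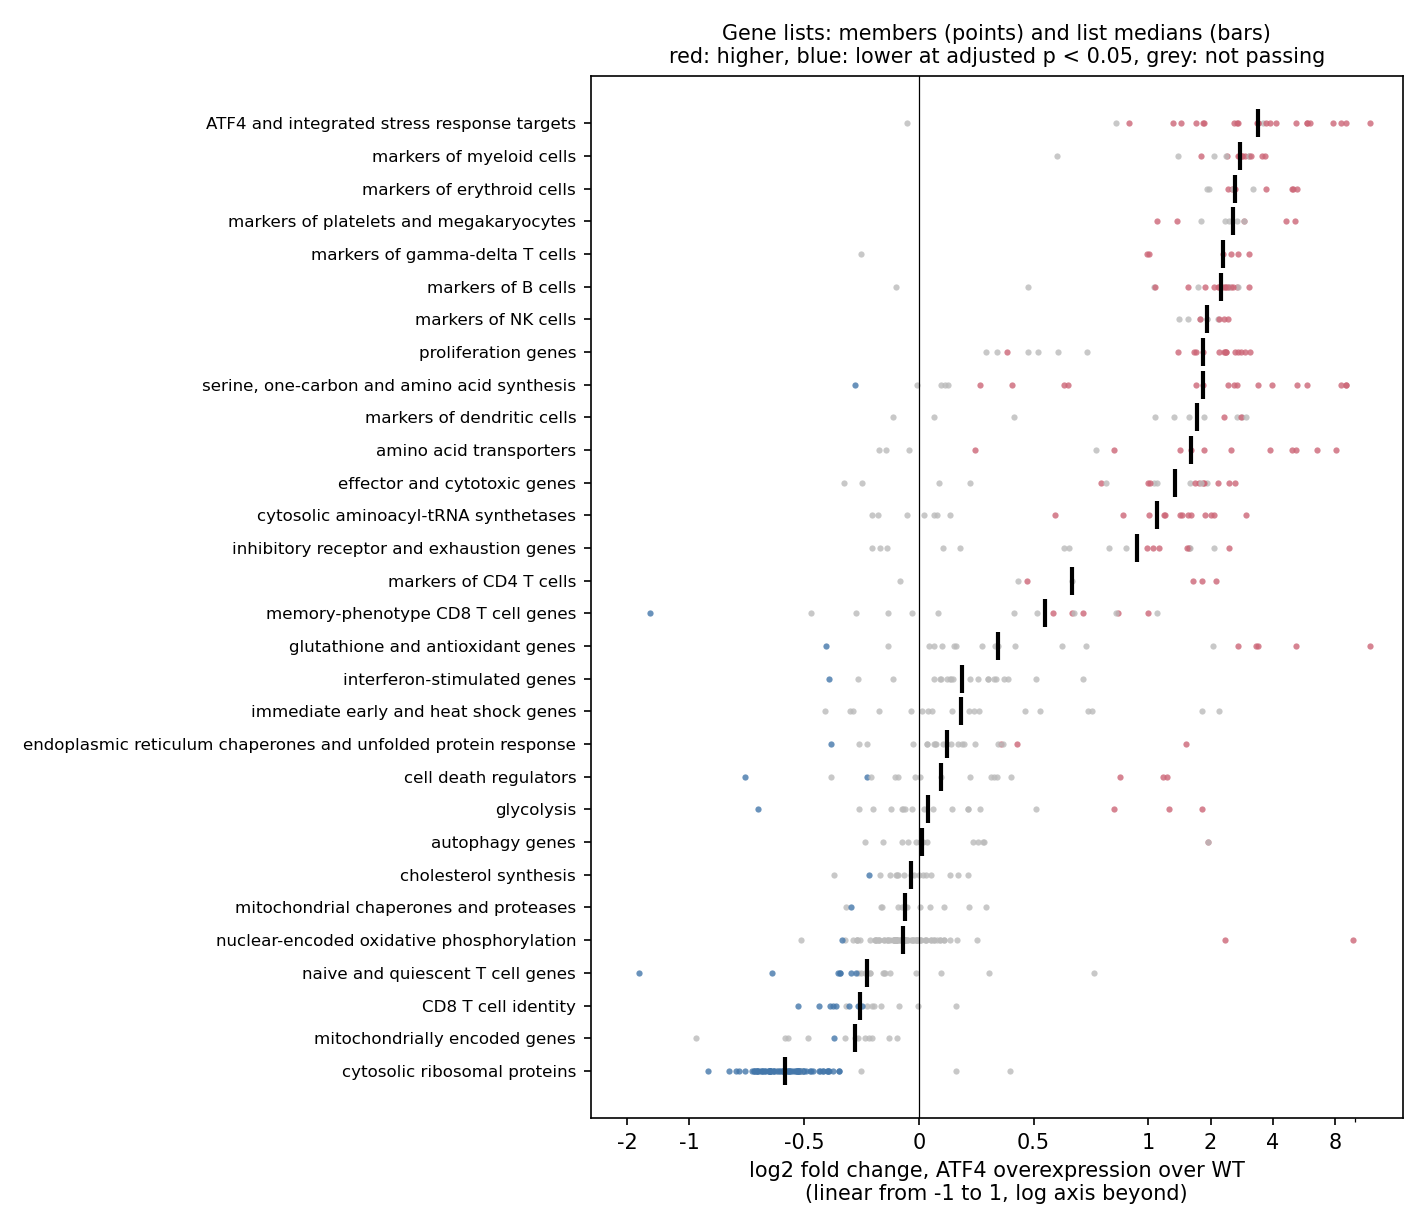
Log2 fold change (ATF4 overexpression over WT, linear between -1 and 1 and logarithmic beyond) of each tested member of 30 gene lists as points, red where higher and blue where lower at an adjusted p below 0.05 and grey otherwise, with a bar at the list median. Genes at 0 in all libraries of a group are drawn at their bound against 3 counts, and ATF4 targets have the highest median (3.38) and ribosomal proteins the lowest (-0.58).

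Genes of the CD8 T cell itself were lower by a small amount. Of 16 CD8 T cell identity genes 8 were lower and 0 higher (11 lower over the list alone), with a median of -0.26 (camera, adjusted p = 2.2e-05; adjusted p = 0.029 with an estimated correlation). Cd8a fell from 1395 ± 106 to 1085 ± 73.8 CPM (log2 fold change -0.36 ± 0.08, adjusted p = 0.013) and Cd8b1 from 1239 ± 80.0 to 947 ± 46.0 CPM (-0.39 ± 0.07, adjusted p = 0.0055). Without the 4 libraries that lack low counts the calls of Cd8a (-0.35, adjusted p = 0.11) and Cd8b1 (-0.38, adjusted p = 0.073) were lost, and that of Cd8b1 within set 1 as well (adjusted p = 0.090). In the same libraries markers of myeloid, B, erythroid and platelet cells were higher, with medians of 2.78, 2.25, 2.61 and 2.57. Of 20 naive and quiescent T cell genes 7 were lower and 0 higher, with a median of -0.23. Over the list alone 10 were lower and 2 higher, and with the replicate block 14 and 1. Its camera call (adjusted p = 3.2e-04) was lost with an estimated correlation (adjusted p = 0.11). Dapl1, a gene of resting naive T cells, fell from 159 ± 13.7 to 47.0 ± 4.29 CPM, and Il7r, the receptor of the survival cytokine IL-7, from 645 ± 29.8 to 414 ± 34.2 CPM.

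Lists of T cell activation were higher, in parallel with markers of other cell types. Effector and cytotoxic genes were higher in 10 of 20 members and lower in 0 (13 higher over the list alone), with a median of 1.34 (camera, adjusted p = 1.6e-05; adjusted p = 0.20 with an estimated correlation). Zeb2, a transcription factor of effector cells, rose from 4.38 ± 1.06 to 27.3 ± 5.39 CPM and Il2ra, the high-affinity chain of the IL-2 receptor, from 2.45 ± 1.00 to 8.91 ± 1.44 CPM. The mean log2 CPM difference of this list was 1.89 in set 1 and 0.60 in set 2, and markers of NK cells, which share effector genes, differed by 3.61 in set 1 and 0.46 in set 2. Inhibitory receptor and exhaustion genes were higher in 6 of 18 members and lower in 0 (8 higher over the list alone), with a median of 0.95 (camera, adjusted p = 7.3e-04; adjusted p = 0.029 with an estimated correlation). Nt5e, the ectoenzyme CD73, rose from 63.9 ± 2.73 to 127 ± 4.66 CPM, and Tigit from 1.63 to 4.71 CPM. The replicate block called 9 members higher and 1 lower. The call of this list was lost without the 4 libraries that lack low counts (adjusted p = 0.053).

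Proliferation genes were higher in 15 of 21 members and lower in 0 (18 higher over the list alone), with a median of 1.85 (camera, adjusted p = 1.4e-08; adjusted p = 0.28 with an estimated correlation). Mki67, a marker of cycling cells, rose by 2.93 ± 0.35 on the log2 scale to 167 ± 74.4 CPM and Birc5, a mitotic survival protein, from 3.66 to 18.4 CPM. The list differed by 1.29 in set 1 and 1.94 in set 2, and markers of erythroid cells by 1.83 and 4.50. Memory-phenotype genes were mixed, with 5 of 16 higher and 1 lower (7 and 2 over the list alone), a median of 0.55 and no camera call (adjusted p = 0.055). Camera called the list higher on voom values (adjusted p = 0.023), without a low-count filter (adjusted p = 0.045), with the stricter filter (adjusted p = 0.033), within set 1 (adjusted p = 0.0014) and without WT replicate 3 or 4 or ATF4 overexpression replicate 4 (adjusted p between 0.017 and 0.033). With an estimated correlation its adjusted p was 0.54, and within set 2 it was 0.93. Cd44 rose from 51.3 ± 8.74 to 81.6 ± 8.78 CPM and Il2rb from 369 to 553 CPM, and Gzmm, a granzyme, fell by 1.55 on the log2 scale. The calls of Cd44 (adjusted p = 0.057) and Il2rb (adjusted p = 0.13) were lost without the 4 libraries that lack low counts.

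Markers of cell types other than CD8 T cells were higher in ATF4 overexpression. Myeloid markers were higher in 11 of 16 members (median 2.78), B cell markers in 14 of 20 (2.25), erythroid markers in 8 of 12 (2.61), platelet and megakaryocyte markers in 5 of 10 (2.57), NK cell markers in 4 of 10 (1.91), dendritic cell markers in 2 of 12 (1.72), gamma-delta T cell markers in 6 of 7 (2.29) and CD4 T cell markers in 4 of 7 (0.67). No member of these 8 lists was lower. Over each list alone, in the same order, 14, 18, 8, 9, 10, 3, 6 and 4 members were higher. Camera called all 8, and with an estimated correlation the myeloid (adjusted p = 0.0095), platelet (adjusted p = 0.014) and gamma-delta (adjusted p = 0.029) lists held. With an estimated correlation the adjusted p was 0.28 for B cells, 0.30 for NK cells, 0.15 for erythroid cells, 0.075 for dendritic cells and 0.11 for CD4 T cells. H2-Aa, an antigen presentation gene, went from 12.3 ± 4.25 to 45.2 ± 23.6 CPM, Csf1r from 3.03 ± 1.28 to 20.2 ± 5.82 CPM and Car1 from 3.27 ± 0.77 to 107 ± 78.5 CPM. The call of H2-Aa was lost without a low-count filter (adjusted p = 0.053) and without the 4 libraries that lack low counts, where its log2 fold change of 1.87 became 1.02 (adjusted p = 0.11).

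NK cell markers depended on the library set. Ncr1 rose by 4.36 on the log2 scale within set 1 and by 0.62 within set 2, and the interaction was past the test (adjusted p = 1.3e-05). With the replicate block 1 of the 10 NK cell markers was higher, and the calls of Ncr1 (adjusted p = 0.24), Tyrobp (adjusted p = 0.098), Klra9 (adjusted p = 0.11), Ccl5 (adjusted p = 0.086) and Cd4 (adjusted p = 0.21) were lost. Ncr1 was also lost in each fit without 1 library (adjusted p between 0.058 and 0.094). Cd4 was at 2.64 ± 1.32 CPM in WT and 9.31 ± 5.65 CPM in ATF4 overexpression (adjusted p = 0.046), a call that held only without ATF4 overexpression replicate 3 or 4 among the fits without 1 library (adjusted p between 0.037 and 0.12). Tyrobp was also lost without ATF4 overexpression replicate 3 (adjusted p = 0.065), and Klra9 without WT replicate 1 or 2 or ATF4 overexpression replicate 2 (adjusted p between 0.051 and 0.057). The camera calls of the NK cell list (adjusted p = 0.051) and of the CD4 T cell list (adjusted p = 0.064) were lost within set 2, and that of the dendritic cell list with the stricter low-count filter (adjusted p = 0.097). Of the 2 dendritic cell markers called, Flt3 was lost without WT replicate 1 or ATF4 overexpression replicate 3 or 4 (adjusted p between 0.056 and 0.059), and of the platelet markers Gp1ba without ATF4 overexpression replicate 4 (adjusted p = 0.069). With the library set as the block Ncr1 (adjusted p = 0.12) and Cd4 (adjusted p = 0.11) were lost. Without a low-count filter Ncr1 (adjusted p = 0.13), Cd4 (adjusted p = 0.10) and Tyrobp (adjusted p = 0.079) were lost, and with limma-voom Ncr1 (adjusted p = 0.064) and Cd4 (adjusted p = 0.10). Without the 4 libraries that lack low counts Ncr1, Tyrobp, Klra9, Ccl5, Cd4 and Flt3 were lost (adjusted p between 0.12 and 0.33), as was the camera call of the CD4 T cell list (adjusted p = 0.090), within set 1 Flt3 (adjusted p = 0.057) and Gp1ba (adjusted p = 0.35), and within set 2 Klra9 (adjusted p = 0.054) and Cd4 (adjusted p = 0.38). In all, 166 genes had an interaction of genotype and library set (edgeR, adjusted p below 0.05).

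**Figure D3:**
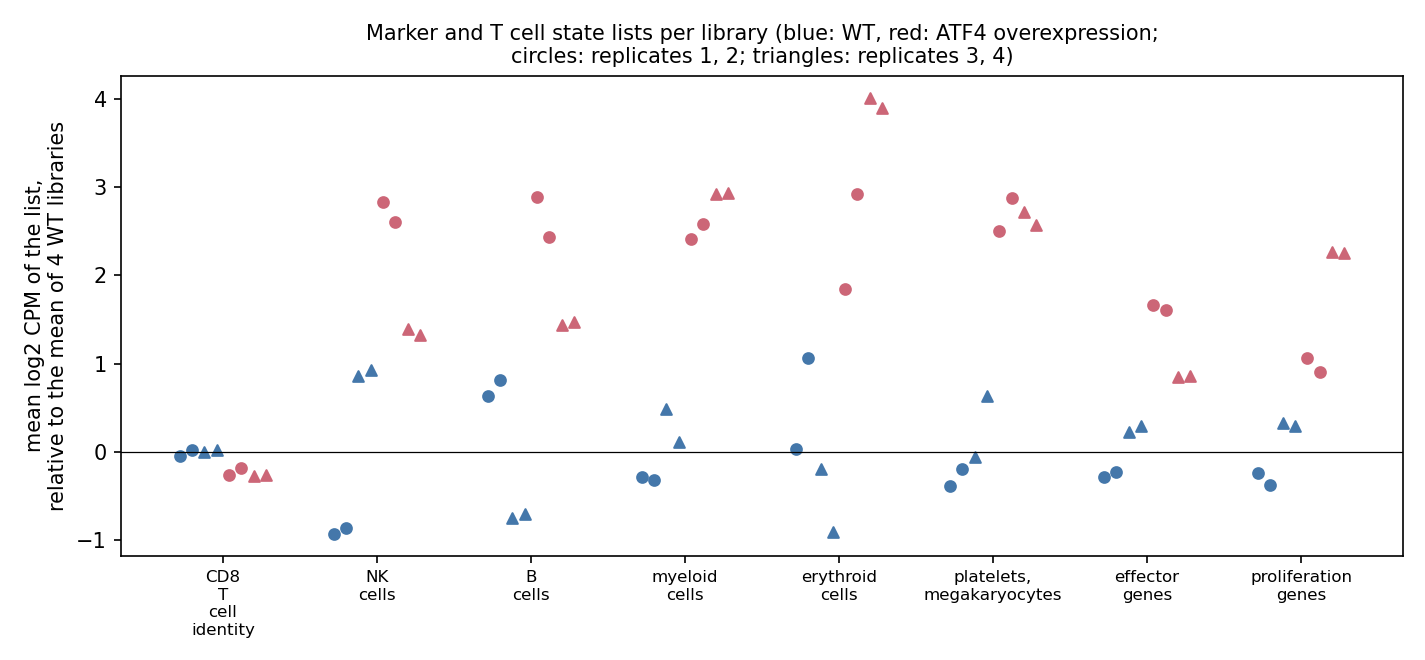
Mean log2 CPM of 8 gene lists in each library, relative to the mean of the 4 WT libraries (blue: WT, red: ATF4 overexpression, circles: replicates 1 and 2, triangles: replicates 3 and 4). The lists of other cell types lie higher in the ATF4 overexpression libraries of each set, by 3.61 for NK cells in set 1 and 0.46 in set 2, while CD8 T cell identity genes lie slightly lower.

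Among the largest single changes, Cox6a2, the muscle form of a cytochrome c oxidase subunit (chromosome 7, 128205435 to 128206387), went from 0.0890 ± 0.0332 to 79.3 ± 13.2 CPM (log2 fold change 9.79 ± 0.23, adjusted p = 1.1e-08). Clic4, an intracellular chloride channel protein, rose from a mean of 25.7 to 265 CPM (3.36 ± 0.10 on the log2 scale). Cdk15 and Tox3 had 0 counts in WT and were at least 379-fold and at least 247-fold higher. Prkg1 had 1 count in WT and 536 in ATF4 overexpression, a ratio of 488 (95% interval 87.3 to 19321). Ighv1-64, an immunoglobulin segment, was at least 285-fold higher, with most of its counts in 1 library. Its call held only without ATF4 overexpression replicate 1 or 2 among the 8 fits without 1 library (adjusted p between 0.026 and 0.073).

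Of the genes that fell, Exosc6 had 0 counts in all 4 ATF4 overexpression libraries and 419 to 657 in WT, at least 842-fold lower. Exosc6 (chromosome 8, 111056339 to 111057664) lies wholly inside the last part of Aars (111033144 to 111057664, same strand, named after its values were seen), and its 1326-nucleotide transcript is contained in the longest Aars transcript of 5750 nucleotides, so its reads are shared with Aars. Aars rose from 62.9 ± 7.99 to 266 ± 26.3 CPM. Gt(ROSA)26Sor, the transcript of the Rosa26 locus often used for transgenes (chromosome 6, 113067428 to 113077333, minus strand), fell from 10.8 ± 2.87 to 0.653 ± 0.41 CPM (log2 fold change -4.05 ± 0.43, adjusted p = 3.1e-04). It overlaps Thumpd3 on the other strand, also named after its values were seen, which was at 64.4 and 61.7 CPM (adjusted p = 0.64). Prss12, a secreted protease, fell from 16.5 ± 5.86 to 1.37 ± 0.33 CPM. Dntt, the terminal transferase of developing lymphocytes, fell by 1.96, Ms4a4c by 1.83 and Hdgfl3 by 1.21 on the log2 scale. Osbpl6, Syt6, Grm6, Tbc1d30 and Trnp1 fell by 3.05, 2.76, 2.39, 2.07 and 1.92 from levels under 10 CPM. Lman1l fell by 2.30, a call lost without WT replicate 2 (adjusted p = 0.052), within set 1 (adjusted p = 0.062), within set 2 (adjusted p = 0.073) and without the 4 libraries that lack low counts (adjusted p = 0.086). Without these 4 libraries Osbpl6 (adjusted p = 0.054) and Trnp1 (adjusted p = 0.051) were lost, and with limma-voom Syt6 (adjusted p = 0.058).

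Endoplasmic reticulum chaperones had 3 of 21 members higher and 1 lower (the same counts over the list alone, camera adjusted p = 0.068), and Herpud1, of endoplasmic reticulum-associated degradation, rose from 64.4 ± 5.24 to 184 ± 13.3 CPM. With the replicate block this list was called higher (adjusted p = 0.040), with 6 members higher and 2 lower. Without the block its adjusted p was 0.25 with an estimated correlation, and fry (adjusted p = 0.0027), camera on voom values (adjusted p = 0.030) and the stricter filter (adjusted p = 0.028) called it. Camera also called it with upper-quartile factors (adjusted p = 0.049) and within set 2 (adjusted p = 0.0094), but not within set 1. Of its higher members, Pdia6 lost its call in 6 of the 8 fits without 1 library, all but those without ATF4 overexpression replicate 1 or 2 (adjusted p between 0.055 and 0.11 where lost). Xbp1 lost its call without WT replicate 3 or 4 or ATF4 overexpression replicate 1 or 2 (adjusted p between 0.053 and 0.072). Nuclear-encoded oxidative phosphorylation genes had 2 of 77 higher and 1 lower (2 and 0 over the list alone). Their median was -0.07 and their mean 0.08, since Cox6a2 and Cox6b2 rose. The camera adjusted p of 0.055 became 0.031 with the replicate block, which called 3 members higher and 10 lower. With the library set as the block camera did not call the list. Without a block the adjusted p was 0.71 with an estimated correlation and 0.83 with fry, and within set 2 the median was 0.045. Camera called the list lower on voom values (adjusted p = 0.031), without a low-count filter (adjusted p = 0.041), within set 1 (adjusted p = 2.6e-04) and without WT replicate 1 or 2 or ATF4 overexpression replicate 3 or 4 (adjusted p between 4.7e-04 and 0.038). Glutathione and antioxidant genes had 5 of 19 higher and 1 lower (6 and 1 over the list alone). Their median was 0.34 (camera, adjusted p = 1.3e-04; adjusted p = 0.20 with an estimated correlation), and 3 of those higher, Chac1, Sesn2 and Slc7a11, are targets listed above. Cell death regulators had 3 of 17 higher and 2 lower (3 and 3 over the list alone, camera adjusted p = 0.49, fry adjusted p = 0.0083). Bbc3 and Bcl2l11, which promote apoptosis, rose by 1.23 ± 0.18 and by 0.88 ± 0.13. Glycolysis had 3 of 18 higher and 1 lower, over the list alone as well (camera adjusted p = 0.57), with Pfkp at 0.85 and Pdk1 at -0.70. Interferon-stimulated genes had a median of 0.19 in the direction of a rise that did not pass (camera adjusted p = 0.058), with 0 of 20 members higher and 1 lower, Ifit2, and 2 higher in DESeq2. Camera called this list higher on voom values (adjusted p = 0.037), with the stricter filter (adjusted p = 0.032), within set 1 (adjusted p = 2.0e-04) and without WT replicate 4 or ATF4 overexpression replicate 3 or 4 (adjusted p between 0.031 and 0.035). With an estimated correlation its adjusted p was 0.45, and within set 2 it was 0.57. Autophagy had 1 of 16 higher, Gabarapl1 (adjusted p = 0.40). Cholesterol synthesis had 1 of 17 lower, Srebf2, and 0 over the list alone (adjusted p = 0.50). Mitochondrial chaperones and proteases had 1 of 13 lower, Spg7 (adjusted p = 0.33). The call of Srebf2 was lost in each of the 8 fits without 1 library (adjusted p between 0.054 and 0.12). That of Spg7 held only without WT replicate 3 or 4 or ATF4 overexpression replicate 3 (adjusted p between 0.031 and 0.068). Edem1 (-0.38), Uqcrh (-0.34) and Tnfrsf10b (-0.76) were also lower, and each lost its call in 6 of the 8 fits without 1 library. Edem1 held only without WT replicate 4 or ATF4 overexpression replicate 1 (adjusted p between 0.018 and 0.094). Uqcrh held only without WT replicate 1 or ATF4 overexpression replicate 4 (adjusted p between 0.035 and 0.11), and Tnfrsf10b only without WT replicate 3 or ATF4 overexpression replicate 1 (adjusted p between 0.022 and 0.11). With upper-quartile factors Edem1 (adjusted p = 0.053) and Uqcrh (adjusted p = 0.079) were lost as well, and with RLE factors Uqcrh (adjusted p = 0.053). Srebf2 was lost with RLE factors (adjusted p = 0.053), upper-quartile factors (adjusted p = 0.076) and no low-count filter (adjusted p = 0.099). Without the 4 libraries that lack low counts Xbp1, Ifit2, Srebf2, Spg7, Uqcrh and Tnfrsf10b were lost (adjusted p between 0.11 and 0.27). Within set 1 Pdia6, Ifit2, Srebf2, Uqcrh, Tnfrsf10b and Cox6b2 were lost (adjusted p between 0.053 and 0.23), within set 2 Srebf2, Spg7 and Uqcrh (adjusted p between 0.050 and 0.13), and with limma-voom Cox6b2 (adjusted p = 0.064). Ggct (-0.40) and Casp8 (-0.23), named after their values were seen, were lower and were not carried through these fits. Immediate early and heat shock genes had 0 of 18 past the edgeR test without a block (4 at an unadjusted p below 0.05, adjusted p = 0.65 for the list), where DESeq2 called 2 and limma-voom 1. Within set 1 camera called this list higher (median 0.26, adjusted p = 0.027), while its median was -0.42 without the 4 libraries that lack low counts (adjusted p = 0.090). The replicate block called 6 of them higher and 3 lower, among them Egr1 (0.69, adjusted p = 9.3e-04), Ier3 (0.53, adjusted p = 0.031), Btg2 (-0.31, adjusted p = 0.0011) and Egr2 (-0.42, adjusted p = 0.031). In other lists with few calls the block gave, higher and lower, 3 and 1 interferon-stimulated genes, 1 and 3 mitochondrial chaperones and proteases, 1 and 1 autophagy genes, 0 and 2 cholesterol synthesis genes, 7 and 3 glycolysis genes and 5 and 4 cell death regulators. Genes that gained a call in this way were Oas1a (0.33, adjusted p = 0.026), Zbp1 (0.22, adjusted p = 0.041), Hspa9 (0.22, adjusted p = 0.0054), Hspe1 (-0.32, adjusted p = 0.018), Atg5 (-0.23, adjusted p = 0.027) and Insig1 (-0.37, adjusted p = 0.0024). Of these 6, Atg5 was not called with the library set as the block (adjusted p = 0.068).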

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

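All tests in this part were chosen after the results they bear on were seen, except the search for samples far from their group and the counts over other splits of the libraries. Of 285 groups of 4 libraries searched, 6 held a library far from the other 3 by Dixon's ratio at its 95% critical value, 2.11%, where chance flags about 1 in 20 groups. Ighv1-64 had a ratio of 0.94 in ATF4 overexpression, with 6.54 CPM in replicate 1 and 0.113 to 0.519 CPM in the others. Eif4ebp1 (0.89, replicate 1 at 40.2 CPM against 46.0 to 46.8), Yars (0.86, replicate 2 at 132 CPM against 153 to 156) and Ulk1 (0.83, replicate 3 at 49.3 CPM against 53.5 to 54.3) each had a low library in ATF4 overexpression. Chac1 in WT replicate 3 (ratio 1, 0.025 CPM) and Prkg1 in WT replicate 4 (ratio 1, 0.008 CPM) rest on 3 counts and 1 count where the other WT libraries had 0.

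Markers of myeloid, B, erythroid, platelet and NK cells were higher in ATF4 overexpression libraries. A lower share of CD8 T cells alone would raise all of them alike. Within library set 2 the mean log2 CPM difference of the other markers exceeded that of NK markers by 2.35 ± 0.25 (SE over marker genes). The difference was 2.18 for B, 2.62 for myeloid, 4.50 for erythroid and 2.35 for platelet markers, against 0.46 for NK markers. This argues against that explanation in the libraries of set 2, although marker genes are not independent and the SE holds no spread between libraries. RNA of several other cell types, each in its own amount, stays open as a candidate explanation, since the bead enrichment used does not remove every other cell. The lowest share of members with a positive log2 fold change over 6 marker lists was 91.7%. It was 85.7% in the CD4 and in the gamma-delta T cell list, which were left out of this check. The lists had already been seen to be higher, so these shares repeat that observation and do not decide between explanations. Of 3 abundant transcripts picked outside the rule for named genes, after their values were seen, Cd74 rose from 33.6 to 152 CPM and Hbb-bs from 1.27 to 7.78 CPM. Lyz2, at 22.9 and 96.8 CPM, did not pass the test (adjusted p = 0.26). The rise of effector genes was larger in set 1, where NK markers differed more, by 1.29 ± 0.25. RNA of NK cells may account for part of it, although Gzma stands in both lists. Members of the effector list differed in this. In ATF4 overexpression Fasl was at 12.6 and 14.5 CPM in set 1 and at 5.37 and 6.22 CPM in set 2. Zeb2 did not follow the NK markers, at 24.1 and 21.6 CPM in set 1 and 29.8 and 33.5 CPM in set 2. The rise of proliferation genes was smaller in set 1 (-0.65 ± 0.12), where erythroid markers differed less. RNA of erythroid precursors may account for part of it. Both SEs are over the genes of a list and hold no spread between libraries. A change of the marker genes by the ATF4 transgene within CD8 T cells cannot be told apart from a change in cell composition. All 4 ATF4 overexpression libraries had a myeloid score above every WT library, and no purity is given in the sources used here.

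Exosc6 had 0 counts in ATF4 overexpression while Aars, which contains it, rose. A change of the chromosomal region is argued against by a median log2 fold change of -0.059 over 14 other tested genes within 500 kb, of which 0 were called lower and 3 higher. Assignment of shared reads to Aars stays open as a candidate explanation, since 100% of the Exosc6 bases lie in Aars exons on the same strand. Loss of Exosc6 transcription in these cells was not tested.

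Gt(ROSA)26Sor, the transcript of the locus often used for transgenes, fell in ATF4 overexpression. A change of the chromosomal region is argued against by a median log2 fold change of 0.015 over 24 other tested genes within 500 kb, of which 0 were called lower and 5 higher. An insertion in this locus that the WT libraries do not share stays open without support from a test, since the fall within both library sets (-3.74 in the weaker) repeats the observation that raised it. The labels do not say where the transgene lies. The design text names control mice that carry it without Cre, which leaves open what genotype the WT libraries had.

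Other splits of the 8 libraries into 4 and 4, 35 in all, were tested as the groups were. For genes higher, 1 of 35 splits, the real one, reached 1524 (highest other 885). The libraries fall into 2 sets and are not freely exchangeable, so this count does not exclude chance, and exchange within sets allows 36 assignments with a smallest p of 0.056 in an exact permutation. For genes lower, 2 of 35 splits reached 813 in a direction, the real one and the split by library set, which called 885 and 536 genes. Which direction counts as lower is arbitrary outside the real split, so 813 was set against the larger direction of the set split. In its smaller direction the set split called 536 genes, fewer than 813, and no split besides these 2 called a gene. The set split follows a difference between libraries, so the count of 2 does not decide on chance. Chance is not excluded here either, since the libraries are not freely exchangeable. With the replicate block 2237 genes were lower. For gene lists, 3 of 35 splits called as many as the real 20 (highest other 24), but the others that did so held 3 libraries of one group and 1 of the other and keep part of the group difference. Such splits called 13 to 24 lists, and the 18 splits of 2 and 2 at most 10. Of the 8 splits that part all 4 same-numbered pairs, the 7 others called 0 genes in edgeR and up to 22 lists.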

How the results depend on the processing

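The fits with the library set, within each set, without the 4 libraries that lack low counts and over genes of at least 10 CPM were chosen after seeing the data, and the other alternatives were chosen before the data were examined. Of the named genes over all alternatives, 2550 values kept direction and side of the threshold, 175 lost the call, 62 gained it and 5 turned direction, and of the lists 565, 19, 30 and 15. Under RLE, upper-quartile factors, both filters, limma-voom and library sizes without mitochondrially encoded genes and Atf4, genes higher ranged from 1321 to 1626, genes lower from 643 to 822, lists called (not run with limma-voom) from 20 to 22 and Atf4 from 0.49 to 0.55. DESeq2 called 2334 higher and 1093 lower. The replicate block gave 2237 genes lower and Atf4 at 0.48, now called, the library set block 2327 higher, 1927 lower and Atf4 at 0.48. Set 1 alone gave 528 lower and Atf4 at 0.59, set 2 alone 2434 higher, 1365 lower and Atf4 at 0.41. Without 1 library at a time, 518 (without ATF4 overexpression replicate 4) to 677 genes were lower, 1089 to 1431 higher, and Atf4 was between 0.32 and 0.67. Without the 4 libraries that lack low counts 333 genes were lower and Atf4 was at -0.11, a fit of 2 libraries per group unbalanced over the sets. Over genes of at least 10 CPM 501 were higher, fewer than were lower, since most of the genes called higher were of low abundance. Camera with an estimated correlation called 9 lists, fry 21 and camera on voom values 24. Xist turned to -0.11 in set 1 and -0.088 without the 4 libraries, and ranged from -0.095 to 0.27 without 1 library. Directions turned for lists that were not called. Immediate early genes had medians of -0.046 to 0.42 without 1 library and -0.42 without the 4 libraries. In set 2 the direction of the test or median turned for mitochondrial chaperones (0.030), oxidative phosphorylation (0.045), autophagy (0.0062), cholesterol synthesis (0.058), memory genes (0.13) and interferon-stimulated genes (0.0010). Without the 4 libraries it turned for mitochondrial chaperones (0.011), oxidative phosphorylation (0.054), autophagy (-0.057) and cholesterol synthesis (0.15). Where no construction is named, the cause was not tested. The alternatives planned for normalized values (another pseudocount, no filter on low values) were not run, since the table held counts. Depth limits only genes of few counts, and most of the spread is between libraries.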

Other observations

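In this part the genes of the first paragraph and the tests of other transcripts with a 5' terminal oligopyrimidine tract and of length alone were chosen after the values were seen, and the test on length and level before. Vegfa, a growth factor of blood vessels, went from 0.704 ± 0.421 to 186 ± 28.6 CPM (log2 fold change 8.07 ± 0.49, adjusted p = 2.6e-05) and was higher in all 4 ATF4 overexpression libraries. Xpot, an exporter of tRNA from the nucleus, went from 55.8 ± 1.38 to 133 ± 9.71 CPM, and Eif2s2, a subunit of the initiation factor eIF2, from 116 ± 4.19 to 238 ± 9.36 CPM. Ikzf2, the transcription factor Helios, went from 28.3 ± 7.26 to 86.5 ± 5.38 CPM. Pde2a, a phosphodiesterase, fell from 287 ± 43.8 to 102 ± 15.4 CPM, and Slc28a2b, a nucleoside transporter gene, from 225 ± 17.1 to 61.6 ± 15.1 CPM. Kit rose from 2.90 ± 0.56 to 46.5 ± 27.3 CPM, Gata1 from 2.06 ± 0.82 to 15.8 ± 9.46 CPM and Mfsd2b from 3.68 ± 0.57 to 55.4 ± 32.2 CPM. Kit rose by 3.20 in set 1 and 4.43 in set 2 on the log2 scale (interaction adjusted p = 0.031 in edgeR).

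Ribosomal protein transcripts start with a 5' terminal oligopyrimidine tract, whose translation and stability depend on mTORC1. If that tract set the fall, other transcripts with it would fall too. A list of 22 such transcripts that encode no ribosomal protein had 14 lower and 0 higher, with a median of -0.33 (camera p = 1.3e-09; p = 0.024 with an estimated correlation). Tpt1 fell from 5867 ± 98.7 to 3649 ± 140 CPM, and Eef1b2 from 1127 ± 49.8 to 692 ± 75.4 CPM, among the larger falls of the list. Members that did not pass the edgeR test included Pabpc1 (-0.04, adjusted p = 0.85), Eif3l (-0.06, adjusted p = 0.75) and Hnrnpa1 (-0.09, adjusted p = 0.58). A list of 40 genes with initiation factor symbols outside complex 3 had 3 higher and 1 lower, with a median of 0.024 (camera p = 0.54; p = 0.77 with an estimated correlation). It was picked by symbol, so it also holds eIF2 kinases and inhibitory binding proteins such as Eif4ebp1, one of the higher genes, and it shares Eif4b with the list above. A change that follows this tract may therefore account for part of the fall, but the 2 lists were not matched on level. A change in cell composition was not tested as a cause of the fall. CD8 T cell identity genes had a median of -0.26, against -0.33 for the other transcripts with the tract and -0.58 for ribosomal proteins. Short transcript length alone is argued against: 81 other genes of at least 10 CPM matched on length (median 1051 nucleotides against 1049) had a median of -0.061, above the ribosomal median by 0.52 (95% interval 0.46 to 0.59). The 39 nuclear-encoded oxidative phosphorylation genes no longer than the ribosomal median had a median of -0.076, with 1 lower. These genes are expressed below the ribosomal ones, so short length together with a high level stays open. Genes matched to the ribosomal ones on length and level had a median of -0.21, above the ribosomal median by 0.37 (95% interval 0.31 to 0.43), and a difference over 0.3 was set beforehand to count against length. The matched genes had a median length of 1743 nucleotides against 1049, so they were not short enough for that bound to hold. This condition on length was added after the difference was seen, and short length at a high level cannot be told apart from the tract by this test.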
